A study of Chlorocebus aethiops with 8 samples.

How the data were processed

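RNA from COS cells, a kidney cell line of the African green monkey, was measured on 8 Affymetrix rhesus macaque arrays, so that probes of a related species read the transcripts. Per the labels, cells received siRNAs against RNA helicase A (RHA, encoded by DHX9) or scrambled siRNAs at 0.5 nM. The RHA siRNAs were directed to nucleotides 2701 to 2721 and 2784 to 2803 of the human coding sequence. Cells on 7 plates of 100 mm were kept 4 h without serum and then 24 h in medium with 10% serum, split and transfected again. Polysomes were isolated from cytoplasmic lysates by sucrose gradients, and 25 ng of total RNA was amplified and biotin-labelled per array. There were 4 groups of 2 arrays: cytoplasmic and polysomal RNA, each under control and RHA siRNA.

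The deposited values are probe set intensity values on a linear scale, with array medians close to each other, and were taken as already normalised by the submitters. The submitters' processing notes name GCOS and RMA with no version and no role. Probe-level files, scan dates and detection calls were not used here. The table held 52865 probe sets, of which 99 were Affymetrix controls. Of all probe sets, 24972 carried 1 gene symbol, 358 carried several and 27535 were not listed with a gene in the probe annotation. Values were put on the log2 scale. The 26383 probe sets with the higher mean log2 value over all 8 arrays, 50% of the 52766 that were not controls, were tested, which set a limit of 4.32 (an intensity of 19.9). They included 16072 with 1 symbol, for 10106 genes. For arrays there is no read depth, and the number of arrays limits the precision.

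Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) as a model of 4 groups with no further term, over all 8 arrays. There were 6 contrasts: RHA against control siRNA in cytoplasmic RNA, in polysomal RNA and as the mean of both, the difference between the polysomal and the cytoplasmic siRNA effect (the change in polysome loading), and polysomal against cytoplasmic RNA under each siRNA. Benjamini-Hochberg adjusted p-values under 0.05 counted as changed. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with the brightest probe set of each gene, adjusted over the lists within a contrast. A list's shift is the mean log2 fold change of its genes minus that of all genes. Groups, contrasts, tests, gene lists and the naming rule were fixed before the data were examined.

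Of 30 lists, 25 had at least 5 measured genes and were tested. They held replication-dependent histones, p53 targets, nuclear-encoded oxidative phosphorylation genes, glycolysis and hypoxia genes, proteasome subunits, cytosolic chaperones, unfolded protein response genes, ATF4 targets, DExD/H-box helicases, RISC and miRNA biogenesis genes, AP-1 and immediate-early genes, growth regulators with long or structured 5' UTRs and interferon-stimulated genes. The others held cytosolic and mitochondrial ribosomal proteins, translation factors, G1/S genes, G2/M genes, extracellular matrix genes, cholesterol synthesis genes, splicing factors, zinc-finger genes picked by a ZNF symbol, and markers of kidney tubule epithelium, fibroblasts and leukocytes. The 5 lists with too few measured genes covered nuclear noncoding RNAs, snoRNA hosts, mitochondrial-genome transcripts, selenoproteins and hepatocyte markers, and were not tested. In each contrast the genes named were up to 12 per direction past the threshold without overlap between arrays of the groups, or otherwise the 6 per direction with the smallest p, with up to 4 members per list, DHX9, and JUND (an mRNA known as a translation target of RHA). Genes named outside that rule are marked as chosen after their values were seen.

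The replicate numbers come from the sample titles, and the 4 arrays of each number are called set 1 and set 2. The sets were checked for a batch difference, and one was found, so lists that were called are given within each set and with the call under the replicate number as a term in the model (the replicate block). Other values are pooled over the sets unless a set is named. With 2 arrays per group the numbers were not taken to pair the samples in the planned test. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these arrays.

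The tests were run on simulated data with the same difference between the sets, with 100 probe sets shifted by log2 1 or log2 2. The simulated noise was independent between probe sets, while the estimated correlation of real lists reached 0.197 without the block. For the proteasome list it was 0.221 with the block. The numbers of false calls and of other lists called thus do not carry over to correlated genes. Without the block, limma recovered 0 of 100 at either size in each of the 4 contrasts simulated (both fractions, cytoplasm, polysome, loading change). With the block it recovered 59 at log2 1 and 100 at log2 2 over both fractions, with 19 false calls. In cytoplasm these numbers were 12 and 91 with 6 false calls, in polysomes 13 and 94 with 9, and for the loading change 1 and 39 with 3. A list of 19 genes shifted by 0.5 was called by limma's camera over both fractions (adjusted p = 1.39e-12, or 0.0304 with an estimated correlation), with 0 other lists called. In the polysome contrast these adjusted p-values of limma were 1.53e-07 and 0.0802. With the block they were 2.62e-15 and 0.0717 over both fractions, and 2.36e-08 and 0.173 in polysomes. A true shift of 0.5 was thus missed there with an estimated correlation. The simulated noise held no correlation between genes, so a call lost that way does not by itself show correlated genes.

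Alternatives were the replicate block, no filter or a filter at the top 25%, arrays centred on their median, renewed quantile or cyclic loess normalisation, an offset of 32 before the log, eBayes with trend and robust estimation, array weights, 1 probe set per gene, an adjusted p under 0.10, a 2-fold change without overlap (for the loading change, with the same sign in both sets) in place of a test, only the 4 arrays compared, and each array left out. For lists they were an estimated correlation, fry, the replicate block, no filter, median centring, quantile normalisation, each array left out and the mean of a gene's probe sets. Blocked fits with an array left out, at 0.10, with an estimated correlation or fry, and without an interaction term were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.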

Results

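The data were 8 arrays of RNA from COS cells, 2 for each of 4 groups: cytoplasmic and polysomal RNA from cells given control or RHA siRNA. Median intensity lay between 19.3 and 20.8 on every array. The 2 replicate sets differed strongly: 13535 of 26383 probe sets (51.3%) differed between set 1 and set 2, 7618 of them higher in set 2. Pearson's r across probe sets, which are not independent replicates, was 0.931 to 0.987 between arrays of a set and 0.826 to 0.861 between the arrays of a group. The hybridisation control transcripts, which are added to each sample, had a mean log2 of 10.0 to 10.8 in set 1 and 11.7 to 11.9 in set 2. The cytoplasmic control array of set 1 stood apart, with a median r of 0.949 to its set against at least 0.967 for every other array. No pair of arrays held identical values.

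The first question was whether the siRNA lowered its target. DHX9, the gene of RHA, was read by probe set MmunewRS.268.1.S1_s_at. In cytoplasmic RNA its intensity was 244 and 342 in the control arrays of sets 1 and 2, and 130 and 254 under RHA siRNA. In polysomal RNA it was 359 and 477 in the control arrays, and 97.2 and 269 under RHA siRNA. DHX9 was thus lower under RHA siRNA in 4 of 4 comparisons within a set. The mean of both fractions was 49.5% of control (log2 -1.01, SE 0.42; -1.40 and -0.63 in sets 1 and 2), with 62.9% in cytoplasm (log2 -0.67, SE 0.59) and 39.0% in polysomes (log2 -1.36, SE 0.59). Group means were 8.17 ± 0.34 and 7.51 ± 0.68 in cytoplasm, and 8.69 ± 0.29 and 7.34 ± 1.04 in polysomes (log2 intensity, SD, n = 2, control first). The difference did not pass the test over all probe sets, with an adjusted p in limma of 1.00, or 0.162 with the replicate block, for both fractions. A further 2 DHX9 probe sets were too dim to be tested and had log2 fold changes of -0.67 and -0.31 over both fractions. The first had -0.71 and -0.62 in sets 1 and 2, with -1.33 in cytoplasm and 0.09 in polysomes of set 2. The second had -0.63 in set 1 and 0.005 in set 2, so it was not lower in set 2. A dim probe set with the same symbol but another gene ID had -0.00.

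**Figure D1:**
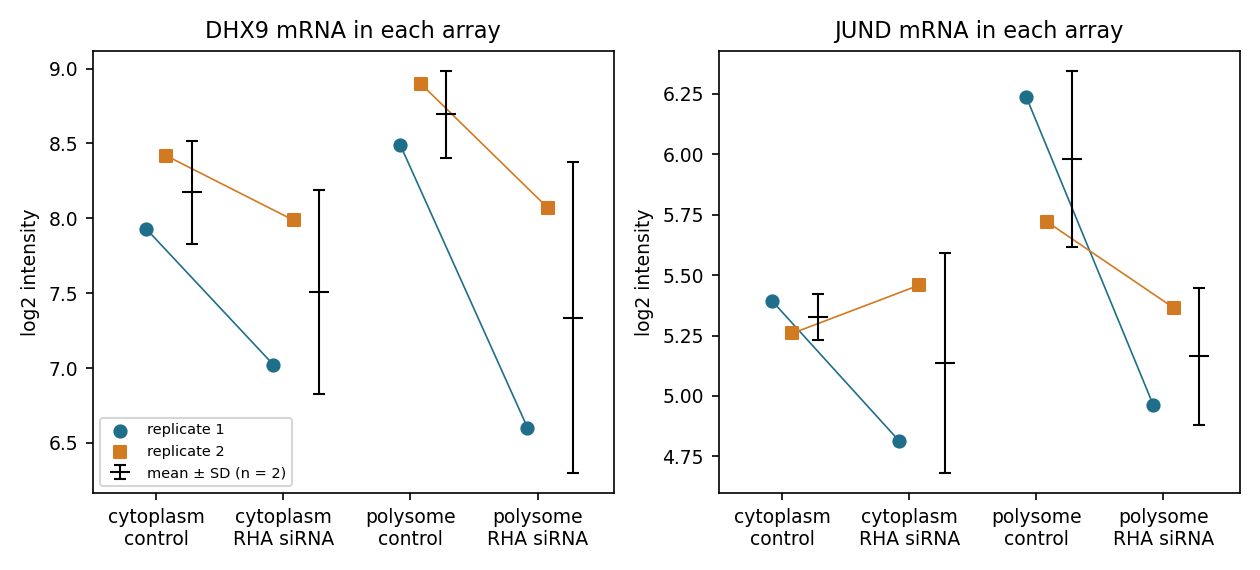
DHX9 and JUND log2 intensity in each array, by fraction and siRNA; circles are replicate 1, squares replicate 2, lines join arrays of a set, and bars are the mean ± SD of 2 arrays. DHX9 was lower under RHA siRNA in each of the 4 comparisons within a set.

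JUND, an AP-1 transcription factor whose mRNA is known as a translation target of RHA, was read by probe set MmugDNA.10738.1.S1_s_at. Its log2 fold change under RHA siRNA was -0.19 in cytoplasm (-0.58 and 0.20 in sets 1 and 2) and -0.82 in polysomes (-1.28 and -0.36). The difference between those, the change in polysome loading of JUND, was -0.63 (SE 0.54; -0.70 and -0.56 in the sets). The log2 ratio of polysomal over cytoplasmic JUND was 0.65 under control siRNA and 0.03 under RHA siRNA. None of these JUND values passed the threshold in limma.

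The mean of both fractions compared 4 RHA siRNA arrays with 4 control arrays and asked which RNAs differed under knockdown wherever they were sampled. H1-2, a linker histone, was 4.44-fold of control (log2 2.15, SE 0.30; 2.18 and 2.12 in sets 1 and 2). SPINK6, a serine protease inhibitor, was 3.24-fold of control, SLC6A15, an amino acid transporter, 2.90-fold, and CREBZF, a bZIP transcription factor, 3.12-fold. GADD45A, a stress-induced growth arrest gene, was 2.09-fold and COG1, a subunit of a Golgi tethering complex, 2.67-fold of control. On the low side, log2 fold changes were -1.55 for EGR2, an immediate-early transcription factor, -1.47 for ME1, the cytosolic malic enzyme, and -1.39 for TOP1, a DNA topoisomerase. They were -1.15 for FBXO8, -1.12 for TMEM150C and -0.93 for SUB1, a transcriptional coactivator. Each of these 12 genes had the same sign in both sets, and none passed the planned threshold. The probe set of H1-2 carries the suffix for probes shared between transcripts, and the same sign was found in 0 of 1 further probe sets of EGR2, 1 of 3 of COG1, 1 of 3 of SUB1 and 1 of 2 of GADD45A. The planned limma test called 0 of 26383 probe sets, with 540 (block: 3156) at an unadjusted p under 0.05 where 1319 would be expected by chance. That fit leaves the set difference in the spread, and in simulated data it recovered 0 of 100 probe sets even at log2 2. Its 0 calls therefore do not show a lack of effect, and the same spread enters the other contrasts. With the replicate block limma called 2, both higher: H1-2 (adjusted p = 0.0458) and a probe set of WWTR1, a Hippo pathway coactivator named here after its value was seen (log2 1.94). Without a test, 62 probe sets were at least 2-fold higher and 42 at least 2-fold lower with no overlap between the groups, a separation that chance gives 2.86% of probe sets before the fold limit if arrays are exchangeable, which the set difference rules out. Within sets at least 2-fold counts were 1013 higher and 309 lower in set 1, against 280 and 264 in set 2. In both sets 37 were at least 2-fold higher and 35 lower, where independent sets would give 10.8 and 3.09, and 19 went opposite ways. The siRNA effects of the sets correlated across probe sets with r = 0.129. With the block and without the cytoplasmic control array of set 2 limma called 954, and without that of set 1 it called 33.

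Replication-dependent histone genes rose as a group over both fractions: 17 of 19 measured members had a log2 fold change above 0, and the list's shift was 0.50 (0.48 in set 1 and 0.51 in set 2). The adjusted p of limma's camera was 1.03e-07, or 4.12e-06 with the replicate block. With an estimated correlation its adjusted p was 0.0769, or 0.489 with the block, which is not past the threshold. Without the block that estimate was -0.016, below the preset 0.01, so correlation between members did not raise the adjusted p there. In simulated data with independent noise the adjusted p of a shifted list was also higher with an estimated correlation. Adjusted over the list alone, 3 members rose in limma: H1-2 (adjusted p = 0.00527), the core histone genes H4C8 (log2 1.03, adjusted p = 0.0383) and H2AC13 (log2 0.94, adjusted p = 0.0464). H2AC13 lay under the limit for testing in the control groups (mean log2 4.06 and 3.84), so its fold is uncertain. Other members lay just above that limit over all arrays, among them H2AC7 (mean log2 4.41), H2AC8 (4.37) and H2BC26 (4.35). Their folds, of log2 0.11, 0.96 and -0.08, are uncertain too. Over all genes 0 members passed without the block, and 7 passed over the list alone with it. Fry, which tests whether a list's genes move one way on balance, gave an adjusted p of 0.0210, or 0.0424 with the block. The histone list was called by limma in each of 8 fits that left out an array, with shifts of 0.39 to 0.61.

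**Figure D2:**
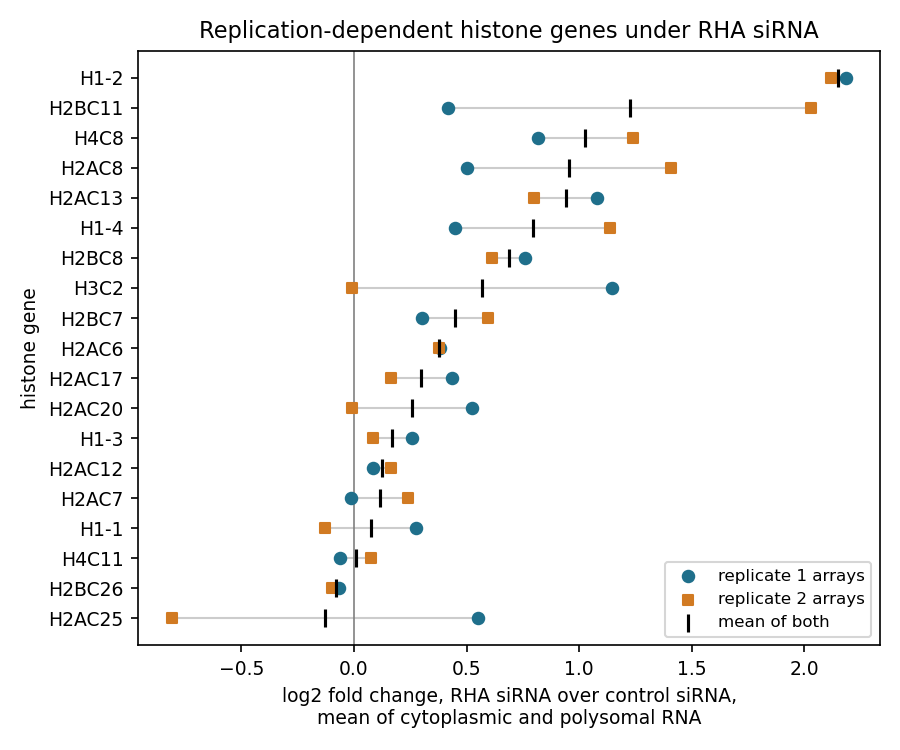
Log2 fold change of the 19 measured replication-dependent histone genes under RHA siRNA, as the mean of cytoplasmic and polysomal RNA; circles are replicate 1 arrays, squares replicate 2 arrays and bars the mean of both. The mean lies above 0 for 17 of 19 genes, and H1-2 lies farthest at 2.15.

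Targets of p53, the DNA damage transcription factor, rose as a group over both fractions, with a shift of 0.28 (0.27 in set 1 and 0.29 in set 2; 12 of 16 members above 0). The adjusted p of limma's camera was 0.0265, against an adjusted p of 0.600 with an estimated correlation and 0.0610 with the replicate block, so the call was lost under both. Adjusted over the list alone, limma called 2 members as risen, GADD45A and the ribonucleotide reductase subunit RRM2B (log2 1.22), each with an adjusted p of 0.0294, and over all genes it called 0. MDM2, which encodes the ubiquitin ligase of p53, had a log2 fold change of 0.84 and TP53I3 one of -0.46. Large T antigen, which binds p53, is expressed in COS cells. The call was lost in 4 of 8 fits that left out an array (the cytoplasmic control of set 2, the cytoplasmic RHA siRNA array of set 1, the polysomal control of set 2 or the polysomal RHA siRNA array of set 1), with shifts of 0.20 to 0.36.

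None of the other 23 lists passed over both fractions. Shifts were 0.25 for unfolded protein response genes (-0.03 in set 1 and 0.54 in set 2; adjusted p in limma = 0.0682), 0.13 for ATF4 targets and 0.26 for RISC and miRNA biogenesis genes. DDIT3, a stress-induced transcription factor, had a log2 fold change of 1.06, and XBP1, a transcription factor of the unfolded protein response, one of 0.80. Among AP-1 and immediate-early genes (shift -0.18) EGR2 fell when adjusted over the list alone (adjusted p in limma = 0.0287), and 0 passed over all genes. The further probe set of EGR2 did not share that sign. Interferon-stimulated genes had a shift of -0.14 (-0.20 in set 1 and -0.08 in set 2), with OAS1 at 0.63 and IFIH1 at -0.66. DExD/H-box helicases had a shift of 0.10, growth regulators with long or structured 5' UTRs 0.08, splicing factors 0.09, translation factors 0.06 and mitochondrial ribosomal proteins 0.10. Cytosolic ribosomal proteins had a shift of -0.03 with a median just above that of all genes. G1/S genes had a shift of -0.06, G2/M genes 0.04 (0.29 in set 1 and -0.20 in set 2), cholesterol synthesis genes -0.10 and extracellular matrix genes 0.11. Shifts were 0.07 for oxidative phosphorylation, 0.04 for glycolysis, 0.10 for the proteasome, 0.19 for cytosolic chaperones and 0.00 for ZNF zinc-finger genes, whose test pointed down. Kidney tubule, fibroblast and leukocyte markers had shifts of -0.10, 0.09 and -0.03.

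Within cytoplasmic RNA, the comparison asked which RNAs differed in abundance under knockdown. H1-2 was 5.24-fold of control (log2 2.39, SE 0.43), DDIT3 2.60-fold, SPINK6 2.82-fold, CREBZF 3.04-fold, and NDUFS8, a subunit of respiratory complex I, 2.26-fold. RAB33A, a small GTPase, had a mean log2 intensity of 5.31 under RHA siRNA and of 3.99 in the controls, where it lay under the limit for testing, so no fold is given. On the low side, log2 fold changes were -1.90 for ME1, -1.61 for TOP1, -1.43 for SUB1, -1.40 for FBXO8, -1.38 for the integrin ITGB8 and -1.35 for TMEM150C. None of these 12 genes passed the threshold: limma called 0 probe sets, with or without the replicate block, at 426 (block: 3174) with an unadjusted p under 0.05. Without a test, 408 probe sets were at least 2-fold higher and 247 lower with no overlap (33.3% by chance before the fold limit, for exchangeable arrays), but the direction of the excess turned between the sets (3169 higher and 796 lower in set 1, against 617 and 1181 in set 2). In both sets 100 were at least 2-fold higher and 115 lower, where independent sets would give 74.1 and 35.6, and 245 went opposite ways. The siRNA effects of the sets correlated with r = 0.0110 across probe sets. With the block and without the cytoplasmic control array of set 2, which leaves the array that stood apart as the lone control, limma called 1150.

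In cytoplasmic RNA 6 lists rose by limma's camera at the preset correlation. With an estimated correlation the adjusted p was 0.291 for histones and 0.532 for each of the other 5 (oxidative phosphorylation, p53 targets, proteasome, glycolysis and chaperones), so none was called. Histone genes had a shift of 0.42 (0.33 in set 1 and 0.50 in set 2; 14 of 19 above 0), and limma's adjusted p was 0.00125, or 0.0208 with the block. Oxidative phosphorylation genes had a shift of 0.21 (0.24 in set 1 and 0.17 in set 2; 45 of 56 above 0), with the ATP synthase subunit ATP5F1B at log2 1.56, and limma's adjusted p was 0.0190, or 0.0237 with the block. The other 4 had adjusted p-values in limma of 0.05 or more with the block (0.0534 each): p53 targets at 0.36 (0.42 in set 1 and 0.31 in set 2), the proteasome at 0.26 (0.48 in set 1 and 0.05 in set 2), glycolysis genes at 0.25 (0.36 in set 1 and 0.15 in set 2) and cytosolic chaperones at 0.31 (0.68 in set 1 and -0.06 in set 2). Without the block their limma adjusted p-values were 0.0308, 0.0443, 0.0443 and 0.0455. Adjusted over the list alone, limma called H1-2 as risen (adjusted p = 0.0206) and no other member of these lists, and over all genes 0. With the block 2 histone genes (H1-2 and H4C8) and 2 p53 targets (GADD45A and RRM2B) rose over the list alone. The mean difference between 3' and 5' probe sets of the control transcripts, a sign of RNA integrity, moved by -1.10 (log2) with RHA siRNA in set 1 and by -0.26 in set 2. Left out in turn, the cytoplasmic control array of set 2 ended the calls of histones, oxidative phosphorylation, p53 targets, proteasome and glycolysis, and that of set 1 those of proteasome, chaperones and glycolysis. The cytoplasmic RHA siRNA array of set 1 ended all but that of histones, that of set 2 ended glycolysis, and either polysomal RHA siRNA array ended chaperones. Without the cytoplasmic control array of set 2 the shifts were 0.49 for histones (adjusted p in limma = 0.0614) and 0.06 for oxidative phosphorylation (0.451). Over all 8 fits they ranged from 0.25 to 0.58 for histones, 0.02 to 0.40 for oxidative phosphorylation, 0.23 to 0.50 for p53 targets, 0.07 to 0.45 for the proteasome, 0.20 to 0.31 for glycolysis and 0.07 to 0.55 for chaperones.

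Within polysomal RNA, the comparison covered both abundance and loading of RNAs on ribosomes. H1-2 was 3.77-fold of control (log2 1.91, SE 0.43), SLC6A15 3.74-fold, SPINK6 3.72-fold, CREBZF 3.21-fold and TMEM216, a protein of the cilium base, 1.99-fold. HMGA2, a chromatin protein, had a mean log2 intensity of 5.80 under RHA siRNA and of 4.26 in the controls, which is under the limit for testing. Log2 fold changes were -1.56 for EGR2, -1.53 for CLIP3, a linker protein of microtubules, -1.42 for BEAN1, -1.18 for NDRG2, -1.17 for TOP1 and -1.12 for UBA1, the enzyme that activates ubiquitin. None of these 12 genes passed the threshold. Limma called 0 probe sets with or without the block, at 137 (block: 1334) with an unadjusted p under 0.05. Without a test, 101 were at least 2-fold higher and 75 lower with no overlap (33.3% by chance before the fold limit, for exchangeable arrays), while at least 2-fold counts were 488 higher and 857 lower in set 1, against 491 and 139 in set 2. In both sets 51 were at least 2-fold higher and 20 lower, where independent sets would give 9.08 and 4.52, and 22 went opposite ways. The siRNA effects of the sets correlated with r = 0.136.

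Histone genes were the single list that rose in polysomal RNA: 18 of 19 members lay above 0 and the shift was 0.58 (0.63 in set 1 and 0.52 in set 2). Limma's adjusted p was 2.01e-09, or 2.52e-08 with the block, and the adjusted p with an estimated correlation was 0.0529, or 0.321 with the block, so the list was not called that way. H2AC13, dim in the controls, had a log2 fold change of 1.14, H4C8 0.97 and H1-4, another linker histone, 0.86. Adjusted over the list alone limma called 0 members, as it did over all genes, and 3 with the block. The difference between 3' and 5' control probe sets moved by 1.19 (log2) in this contrast in set 1 and by -0.33 in set 2. The histone call held in each of 8 fits that left out an array, with shifts of 0.36 to 0.79.

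The change in polysome loading, the question in the title of the series, was tested as the difference between the polysomal and the cytoplasmic siRNA effect. Every array had the same RNA input and a similar median. Only loading relative to other RNAs was thus measured, and a change common to all RNAs would not show. Log2 differences were -1.78 for NDUFS8 (-1.93 and -1.64 in sets 1 and 2), -1.74 for UBA1, -1.71 for HADHB, an enzyme of mitochondrial fatty acid oxidation, and -1.64 for COPS6, a subunit of the COP9 signalosome. They were -1.41 for CLIP3 and -1.26 for CARS2, the mitochondrial cysteinyl-tRNA synthetase. On the high side they were 1.28 for HMGA2 (dim in polysomal controls), 1.09 for the tRNA methyltransferase TRMT11, 1.07 for PHLDA1, 1.05 for the RNA-binding protein HNRNPH2, 1.04 for the tumour suppressor APC and 0.99 for SUB1. For DHX9 the difference was -0.69 (SE 0.84). None of these 13 genes passed the threshold, and limma called 0 probe sets with or without the block, at 46 (block: 1048) with an unadjusted p under 0.05. Without a test, 150 were at least 2-fold higher and 673 lower with the same sign in both sets, which chance gives 50% of probe sets before the fold limit. The excess of lower probe sets came from set 1 (851 higher and 3913 lower in set 1, against 1226 and 554 in set 2), and 55 were at least 2-fold lower in both sets where independent sets would give 82.2. At least 2-fold higher in both sets were 35, where independent sets would give 39.5, and 389 went opposite ways. The differences of the sets correlated with r = -0.0734.

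In polysome loading 3 lists fell by limma's camera at the preset correlation. The same 3 had risen in cytoplasmic RNA, an effect that this contrast subtracts, so these calls are not independent of those. With an estimated correlation none of the 3 was called (adjusted p = 0.717 for oxidative phosphorylation, 0.621 for glycolysis and 0.717 for the proteasome). Oxidative phosphorylation genes had a shift of -0.27 (-0.31 in set 1 and -0.24 in set 2; 42 of 56 below 0), with ATP5F1B at -1.98 (-3.12 and -0.84 in the sets). Glycolysis genes had a shift of -0.43 (-0.68 in set 1 and -0.19 in set 2; 14 of 19 below 0), with pyruvate kinase PKM at -1.63 and triosephosphate isomerase TPI1 at -1.76. Proteasome genes had a shift of -0.32 (-0.59 in set 1 and -0.06 in set 2; 21 of 31 below 0), with PSMD2 at -2.22 (-4.07 and -0.36 in the sets). Limma's adjusted p-values were 0.00554, 0.00448 and 0.0209 in that order, and 0.00924, 0.0142 and 0.0203 with the block. Adjusted over the list alone 0 members passed in limma, as over all genes, and NDUFS8 passed over its list with the block (adjusted p = 0.0466). Splicing factors had a shift of -0.34 (-0.53 in set 1 and -0.15 in set 2) and were called by limma with the block alone (adjusted p = 0.0142), and not with an estimated correlation (adjusted p = 0.717, or 0.885 with the block). Growth regulators with long or structured 5' UTRs had a shift of -0.15 (15 of 18 below 0; adjusted p in limma = 0.332), and histones one of 0.16 with a median just below that of all genes. The difference between 3' and 5' control probe sets moved by 2.29 (log2) in this contrast in set 1 and by -0.07 in set 2. With the block and without the cytoplasmic control array of set 1, oxidative phosphorylation kept its call (-0.28, adjusted p in limma = 0.0109), while the proteasome (-0.18, 0.421) and glycolysis (-0.33, 0.158) lost theirs. With the block, oxidative phosphorylation lost its call without the cytoplasmic RHA siRNA array of set 1 (-0.22, adjusted p in limma = 0.0805) and without the polysomal control array of set 2 (-0.24, 0.0616). Without the block, oxidative phosphorylation lost its call in 4 of 8 fits that left out an array (cytoplasmic control of set 2, cytoplasmic RHA siRNA of set 1, polysomal control of set 1, polysomal RHA siRNA of set 2), the proteasome in 5 (those and the cytoplasmic control of set 1) and glycolysis in 2 (the control arrays of set 1; lowest to highest shift -0.46 to -0.09, -0.51 to -0.14 and -0.56 to -0.31).

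**Figure D3:**
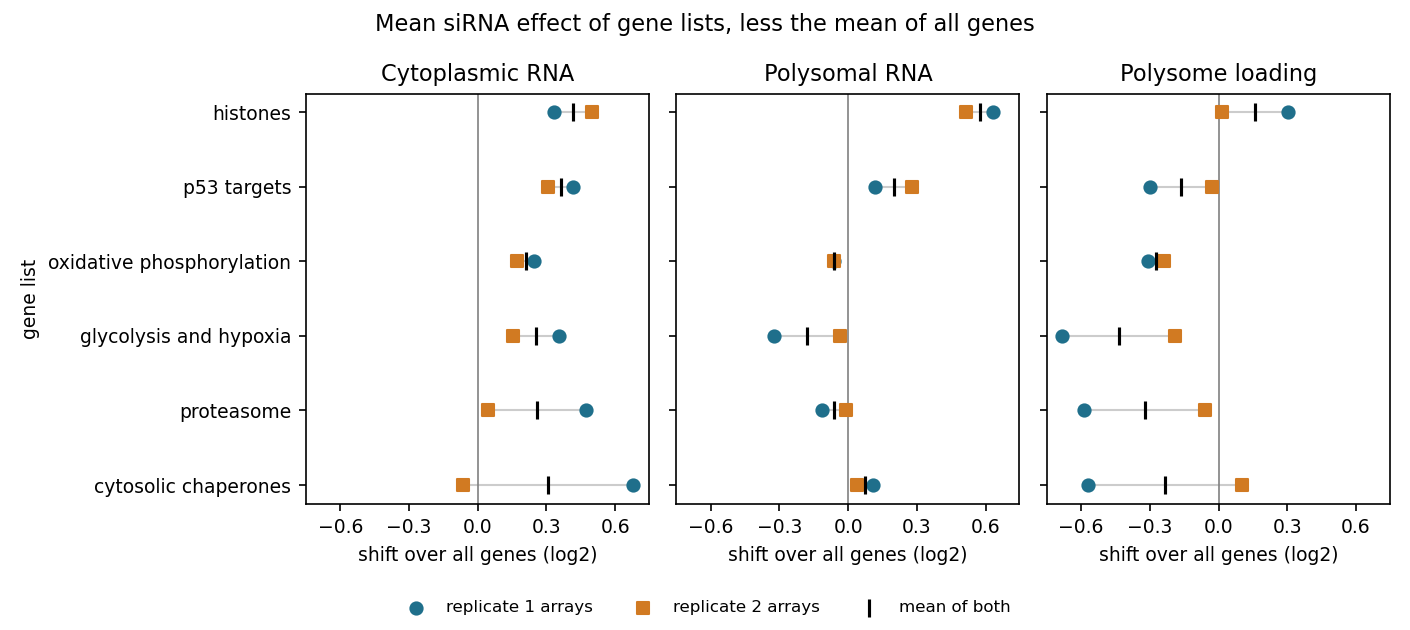
Mean log2 siRNA effect of 6 gene lists, less the mean of all genes, in cytoplasmic RNA, in polysomal RNA and for polysome loading (polysomal minus cytoplasmic effect); circles are replicate 1 arrays, squares replicate 2 arrays and bars the mean of both. Histones lie above 0 in both fractions and both sets, while the proteasome shift in loading is -0.59 in set 1 and -0.06 in set 2.

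Polysomal against cytoplasmic RNA under control siRNA gave the baseline distribution of RNAs. ZC3H18, an RNA-binding zinc-finger protein, was 2.64-fold higher in polysomes and the splicing regulator SFSWAP 2.13-fold. The splicing factor SART1 had a mean log2 intensity of 5.39 in polysomes and of 4.23 in cytoplasm, which is under the limit for testing. UBA1, CLIP3 and MTF1, a metal-responsive transcription factor, had log2 ratios of 1.01, 0.89 and 0.90, and PCIF1, NF1, HSPA12B and MAP6 had -0.89, -0.81, -0.69 and -0.62. The loci LOC718722 and LOC701745 had -0.73 and -0.71, the latter with a polysomal mean of 4.24, under the limit. None passed: limma called 0 probe sets with or without the block, at 55 (block: 1087) with an unadjusted p under 0.05, and 139 were at least 2-fold higher and 8 lower with no overlap (33.3% by chance before the fold limit, for exchangeable arrays). That imbalance came from set 1 and turned in set 2 (2597 higher and 148 lower in set 1, against 53 and 135 in set 2). With the block and without the cytoplasmic control array of set 2, limma called 748. Across probe sets the ratios of the sets correlated with r = -0.0440.

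Under control siRNA limma's camera called 7 lists at the preset correlation and none with an estimated correlation (adjusted p of at least 0.572 for all 7). The 6 called as higher in polysomes were helicases (shift 0.22; 0.33 in set 1 and 0.11 in set 2; 34 of 40 above 0), with DDX41 at 0.85, proteasome genes (0.23), splicing factors (0.21), glycolysis genes (0.20), chaperones (0.18) and oxidative phosphorylation genes (0.12). The shifts in sets 1 and 2 were 0.36 and 0.09 for the proteasome, 0.37 and 0.05 for splicing factors, 0.37 and 0.02 for glycolysis, 0.39 and -0.02 for chaperones and 0.09 and 0.15 for oxidative phosphorylation. The cytoplasmic control arrays are subtracted here as in the cytoplasmic siRNA contrast, and added in the loading change. Calls of proteasome, glycolysis, chaperone and oxidative phosphorylation genes that recur across these contrasts are thus not independent. Leukocyte markers, a negative control list of 6 genes, were called as lower (-0.33, with -0.45 in set 1 and -0.20 in set 2), with CD14 at -0.34. Since a negative control list was called, a call at the preset correlation alone is weak evidence, here and in the other contrasts. Limma's adjusted p was 0.00284 for helicases, 0.0108 for the proteasome and 0.0472 for each of the other 5. With the block limma kept helicases (0.00601), the proteasome (0.0112) and splicing factors (0.0239), and adjusted over the list alone, as over all genes, 0 members passed. With the block and without the cytoplasmic control array of set 1, which had the highest 3' to 5' difference of its set (4.09, against 2.54 in the polysomal control), 0 lists were called. In fits that left out an array without the block, the call was kept in 0 of 8 for glycolysis (shifts 0.08 to 0.32), 1 for oxidative phosphorylation (-0.03 to 0.27), 1 for chaperones (-0.05 to 0.42) and 5 each for helicases (0.10 to 0.34), the proteasome (0.12 to 0.34), splicing factors (-0.05 to 0.47) and leukocyte markers (-0.63 to -0.02). Oxidative phosphorylation kept its call without the cytoplasmic control array of set 1 and chaperones without that of set 2; the losses of these last 4 lists came without control arrays (helicases and proteasome: both cytoplasmic and the polysomal one of set 1; splicing factors and leukocyte markers: both polysomal and the cytoplasmic one of set 1). With the block and without the cytoplasmic control array of set 1 the shift was 0.11 for helicases, 0.08 for the proteasome and 0.08 for splicing factors.

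Polysomal against cytoplasmic RNA was compared in the same way under RHA siRNA. ITGB8 was 2.06-fold higher in polysomes, DENND2C 2.04-fold, APC 1.92-fold, PSPC1, a paraspeckle protein, 1.88-fold, SPG11 1.81-fold and TRMT11 1.80-fold. Log2 ratios were -0.95 for NDUFS8, -0.82 for DUOXA2 (with a polysomal mean of 4.15, under the limit for testing), -0.76 for the mitochondrial peroxidase PRDX3, -0.73 for JTB, and -0.88 and -0.71 for the loci LOC718777 and LOC699389. None passed: limma called 0 probe sets with or without the block, at 70 (block: 1177) with an unadjusted p under 0.05, and 58 were at least 2-fold higher and 21 lower with no overlap (33.3% by chance before the fold limit, for exchangeable arrays), while at least 2-fold counts were 332 higher and 509 lower in set 1, against 515 and 174 in set 2. The ratios of the sets correlated with r = 0.184 across probe sets.

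Under RHA siRNA limma's camera called 4 lists at the preset correlation and none with an estimated correlation (adjusted p = 0.992 for all 4). ZNF zinc-finger genes, picked by symbol (many of this family carry a KRAB repressor domain), were higher in polysomes: 151 of 210 lay above 0, with a shift of 0.17 (0.14 in set 1 and 0.19 in set 2) and ZNF83 at log2 1.21. Cytosolic ribosomal proteins were lower (-0.19; -0.17 in set 1 and -0.21 in set 2; 23 of 36 below 0), with RPL12 at -0.84. Glycolysis genes (-0.24; -0.31 in set 1 and -0.16 in set 2), with GAPDH at -0.74, and oxidative phosphorylation genes (-0.16; -0.22 in set 1 and -0.09 in set 2) were lower too. Limma's adjusted p-values were, for ZNF genes, ribosomal proteins, glycolysis and oxidative phosphorylation, 0.00136, 0.0293, 0.0217 and 0.0417, with 0.00129, 0.0138, 0.0362 and 0.0362 under the block, in the same order. Adjusted over the list alone, as over all genes, limma called 0 members. The difference of ZNF genes from control siRNA was not past the threshold (loading change 0.13, adjusted p in limma = 0.0964), nor was that of ribosomal proteins (-0.04, 0.668). The difference between 3' and 5' control probe sets was 2.98 in cytoplasmic and 3.73 in polysomal RNA in set 1, and 3.56 and 3.82 in set 2. Without the block, each of these 4 calls was lost in at least 2 of 8 fits that left out an array. For all 4 these were the cytoplasmic RHA siRNA array of set 1 and the polysomal one of set 2. Ribosomal proteins and glycolysis also lost theirs without the other 2 RHA siRNA arrays. The shifts were 0.09 to 0.24 for ZNF genes and -0.21 to -0.17 for ribosomal proteins. They were -0.29 to -0.19 for glycolysis and -0.34 to 0.03 for oxidative phosphorylation. With the block, ZNF genes ranged from 0.06 to 0.28 and lost the call without the cytoplasmic RHA siRNA array of set 2 or the polysomal one of set 1.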

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

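The tests of the replicate sets, of S phase, of RNA integrity, of hybridisation controls, of the histone and strongest lists over other splits, and of splits balanced over the sets were chosen after the results were seen. For 3 lists the siRNA effect differed between the fractions by the test of that difference at the preset correlation: oxidative phosphorylation at -0.27 (0.21 in cytoplasm, -0.06 in polysomes), the proteasome at -0.32 (0.26 and -0.06) and glycolysis at -0.43 (0.25 and -0.18). None of the 3 was called with an estimated correlation, where the adjusted p in limma was 0.717, 0.717 and 0.621, and 0.885 for each with the replicate block.

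A technical candidate explanation for those 3 is RNA integrity in set 1, since the 3' to 5' difference moved by 2.29 in this contrast in set 1 and by -0.07 in set 2. In set 2 alone the shift was -0.24 (SE 0.15) for oxidative phosphorylation, -0.19 (SE 0.23) for glycolysis and -0.057 (SE 0.20) for the proteasome. The SE is over genes and widened by their estimated correlation; each set has 1 array per group, so the spread between arrays is not in it. All 3 shifts lay within 2 SE of 0, as did those of set 1, so integrity, an effect of RHA on loading and chance cannot be told apart for any of the 3 lists.

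Histone genes were higher under RHA siRNA in both fractions at the preset correlation and not with an estimated one, and their shift may reflect the knockdown, the arrays or the probes. The lowest of the 3 shifts without the array that stood apart was 0.50 (cytoplasm of set 2), so the shift was not confined to a single set or that array. Its SE of 0.24 is over genes, widened by their correlation but without the spread between arrays. Each of these shifts compares 1 array with 1, so they cannot weigh chance differences between arrays as the cause. The 15 members read by probe sets without the suffix for shared probes had a shift of 0.45 (SE 0.13), which argues against probes shared between paralogs as the whole cause. A larger share of cells in S phase cannot be told apart from a change in histone RNA itself: G1/S genes had a shift of -0.060 (SE 0.09), near 0 with members going both ways. What share of all histone RNA the amplified and labelled RNA represents was not tested, so the shift describes the array signal. Effects of the siRNAs on other targets were not tested, and a biological cause remains a hypothesis found and examined on the same arrays.

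Other splits of the 8 arrays into 4 and 4, with fraction as a term, were fitted with limma to ask about chance. For the histone list, 1 of 34 splits (the real one) gave a p as small (-log10 p of 8.74, highest other 5.14), and 1 of 33 did so with the replicate block (7.18, highest other 7.07, a narrow margin). The strongest of all 25 lists in each split gave the same numbers. For probe sets with the block, 1 of 33 splits called as many as the real 15 (highest other 0). These counts include splits unbalanced over the replicate sets, which carry the set difference, and some of which are the same fit once the block is in the model. Of splits that part each set 2 and 2, like the real one, there were 17, which are too few for a share under 0.05. Among them the real split was 1 of 17 for the histone list (highest other 5.14, or 4.17 with the block), for the strongest list (5.14, or 5.49 with the block) and for probe sets with the block (highest other 0).

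Chance cannot be excluded for the number of lists called: 17 of 34 splits called at least the 2 of the real split (highest other 9), and 30 of 33 called at least 1 with the block (highest other 8). Among the 17 balanced splits these were 14 (highest other 9) and 14 (highest other 7). For probe sets without the block the real split called 0, so that 34 of 34 splits call as many decides nothing. The split along the replicate sets called 13013, which points to a structure of the samples.

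The difference between the replicate sets could be technical, such as labelling or hybridisation. The hybridisation controls, which come from no cell, were 1.52 (log2) higher in set 2 with no overlap between the sets, which is consistent with a technical part. No biological explanation was tested, since the labels give none, and a difference between cultures stays open.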

How the results depend on the processing

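The blocked fits with an array left out, at 0.10, with an estimated correlation or fry, and without an interaction term were added after seeing the data; the rest were set before the data were examined. All of them were run, and named genes below the top 25% have no value under that filter. Without the block the set difference stays in the spread, so a gene that stays below the threshold there says little. Over 166 values of named genes, 1450 of 1451 alternatives that kept all arrays left direction and side of the threshold the same. The remaining 1, H1-2 over both fractions with the replicate block, passed. Of 2656 with an array left out, 19 changed sign and 40 passed. Among alternatives that kept all arrays, the block, the filters and eBayes with trend leave a fold change as it is. For those the direction was fixed in advance. Of 207 alternatives over 23 called lists that kept all arrays, 121 kept the direction and lost the call, and 0 changed direction. The block, an estimated correlation, fry and median centring cannot change a list's shift in this balanced design. The constant direction was thus largely fixed in advance. Where a value moved, the cause was not tested, except where fewer arrays or no test shows it.

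Counts of probe sets were 0 in limma in all 6 contrasts and moved as follows. Over both fractions the replicate block gave 2, the block at 0.10 gave 21 and the block without an interaction term gave 15. A 2-fold change without overlap and without a test gave 655 in cytoplasm, 176 in polysomes, 104 over both fractions, 147 for loading under control siRNA and 79 under RHA siRNA, and a 2-fold difference with the same sign in both sets gave 823 for the loading change. With an array left out, counts ranged from 0 to 1150 in cytoplasm, 0 to 954 over both fractions and 0 to 748 for loading under control siRNA, each highest with the block and without the cytoplasmic control array of set 2, and were 0 in the other 3 contrasts. With an array left out a group has a lone array, assumed to vary like the other groups. DHX9 over both fractions ranged from -1.38 to -0.65 with an array left out, and passed in 1 of those fits (-1.13, with the block and without the cytoplasmic control array of set 2). In cytoplasm DHX9 ranged from -1.15 to -0.19 and in polysomes from -2.09 to -0.62.

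The number of lists called was 6 in cytoplasm, 1 in polysomes, 3 for the loading change, 2 over both fractions, 7 for loading under control siRNA and 4 under RHA siRNA. An estimated correlation gave 0 in all 6, with or without the block, and fry gave 0 except for 1 over both fractions, with or without the block. The block gave 2 in cytoplasm, 4 for the loading change, 1 over both fractions and 3 for loading under control siRNA. Renewed quantile normalisation gave 3 in cytoplasm and 2 in polysomes, median centring gave 4 for loading under control siRNA, and no filter gave 2 in polysomes, 1 over both fractions and 1 for loading under RHA siRNA. The mean of a gene's probe sets gave 5 for the loading change, 1 over both fractions and 1 for loading under RHA siRNA. With an array left out the ranges were 1 to 8 in cytoplasm, 1 to 3 in polysomes, 0 to 7 for the loading change, 1 to 7 over both fractions, 0 to 7 for loading under control siRNA and 0 to 4 under RHA siRNA. With an array left out, direction turned for 4 lists: chaperones (-0.086 to 0.46), splicing factors (-0.050 to 0.47) and oxidative phosphorylation (-0.035 to 0.27) for loading under control siRNA, and oxidative phosphorylation under RHA siRNA (-0.34 to 0.031). The turns came without the cytoplasmic control array of set 1 for chaperones and splicing factors, without that of set 2 or the polysomal control array of set 1 for oxidative phosphorylation, and without the cytoplasmic RHA siRNA array of set 1 under RHA siRNA.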

Other observations

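The fit with fraction, siRNA and replicate number as terms and no interaction, and the genes named from it, were chosen after the values were seen. It called 11 probe sets as risen and 4 as fallen over both fractions in limma, 6 of them without a gene symbol. Beside H1-2 (adjusted p in limma = 0.0115) and WWTR1 (1.94 on the log2 scale), those that rose were SPINK6 (1.69), SUGCT (1.68), SPMAP1 (1.61), NOL4 (1.49) and KDELR2 (1.35), a receptor that returns proteins to the endoplasmic reticulum. TOP1 (-1.39) and EGR2 (-1.55) fell, though the further probe set of EGR2 did not share its sign. Without the block none of these genes passed over all genes in limma. DHX9 itself did not pass in the fit without interaction (adjusted p in limma = 0.145).

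Over both fractions and with the replicate block, the genes named in this paragraph, chosen after the values were seen, had an adjusted p in limma under 0.05 over their list alone. None of these passed over all genes, and without the block, as planned, none passed over its list either (adjusted p in limma = 0.0539 for DDIT3, 0.286 for XBP1, 0.770 for CHAC1 and 0.915 for DERL2). With the block DDIT3 (log2 1.06, adjusted p = 0.00823) and CHAC1, a glutathione-degrading enzyme (log2 0.79, adjusted p = 0.0155), were above 0 among ATF4 targets. XBP1 (log2 0.80) and DERL2 (log2 0.71), a factor of protein export from the endoplasmic reticulum, were above 0 in the unfolded protein response list, each with an adjusted p in limma of 0.0408. Among translation factors EIF4E2 was above 0 (log2 0.84), while EIF3I (-0.90) and EIF4E3 (-0.81) were below 0, and AGO3, an Argonaute protein, was above 0 among RISC genes (log2 0.91). RPS10 (-0.81) was below 0 among ribosomal proteins and COX7A2 (-0.90) among oxidative phosphorylation genes.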
